A study of Daphnia magna with 24 samples.

How the data were processed

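RNA of whole female Daphnia magna juveniles was measured in 24 samples, 3 in each of 8 groups: control, tributyltin, pyriproxyfen and bisphenol A, each at 8 h and 24 h. Total RNA was extracted with Trizol and labelled with Cy3 by a low-input amplification kit, per the labels' protocols, and each sample was hybridised to its own array. Groups and replicate numbers were taken from the sample titles. All 24 arrays carried the same 51424 non-control probes of 60 bases in 59125 spots. The files pair 0 of these probes with a gene name or description, and none was assigned here.

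The deposited scanner files hold spot intensity on a linear scale, with no normalization between arrays, per the file headers. The processed signal in them was background-subtracted and detrended within each array, with surrogate values for dim spots, per the file headers. Scanning software was Agilent Feature Extraction 10.5 per the submitters' processing notes, while the headers give version 10.7.3.1 for 17 arrays read on 1 scanner and 10.5.1.1 for 7 arrays read on another. The 7 arrays were all those of replicate 4 except that of pyriproxyfen at 8 h. The arrays lay on 5 slides, holding 4, 3, 6, 6 and 5 arrays. The authors also deposited log2 values for all arrays, whose scale, centring and direction were worked out from the data. Over bright probes its columns correlated with quantile-normalized log2 processed signals, centred on each probe's median over the 24 arrays, at r of 0.999 or more with slopes between 0.998 and 1.001. The medians of its columns, in the order of the replicate numbers, were 0.00374, 0.000418 and 0.0219 for control at 8 h, -0.00735, -0.00128 and 0.00227 for control at 24 h, -0.000275, 0.0143 and 0.000698 for bisphenol A at 8 h, and 0.00375, -0.00463 and -0.00426 for bisphenol A at 24 h. For pyriproxyfen they were 0.00364, -0.00192 and -0.000264 at 8 h and 0.00247, -0.00225 and -0.0057 at 24 h, and for tributyltin -0.00156, 0.00463 and -0.00222 at 8 h and -0.00237, -0.00235 and -0.00201 at 24 h.

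The processed signals were put on the log2 scale, and each array's 75th percentile over non-control spots was subtracted. Spots with an outlier flag (54 to 319 per array) were left out, and spots of 1 probe were averaged. The 75th percentile signal ranged from 45.8 to 119 between arrays. A probe was tested if it was well above background on all 3 arrays of at least 1 group, which left 13550 probes and 37874 untested ones, and 7978 probes were well above background on all 24 arrays. With between 20.8% and 27.2% of spots well above background, the 75th percentile lay close to the limit of detection, and the scaling was therefore also tried with the percentile over spots detected on all arrays. Replicate arrays of a group correlated at r of 0.908 or more over the tested probes, and no pair of files held the same values. The first principal component held 65.8% of the variance.

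Group differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with version 1.17.8 of the data.table package, as 16 contrasts of the 8 group means over the 24 arrays, with 16 residual degrees of freedom and 2.49 prior degrees of freedom. P-values were two-sided and Benjamini-Hochberg adjusted over the 13550 probes of a contrast, with a threshold of 0.05 and no minimum fold. The contrasts were the 3 chemicals against control at each time, control at 24 h against control at 8 h, the 3 interactions of chemical and time, and the 3 pairs of chemicals at each time. The fit was checked on simulated data in which 50 of 13550 probes changed at each of 4 sizes. In the comparison of bisphenol A with control at 24 h it recovered 94% of probes changed by 3 on the log2 scale, 88% at 2, 46% at 1 and 10% at 0.5. For tributyltin against control at 8 h the shares were 98%, 94%, 52% and 8%, and for pyriproxyfen against control at 8 h 98%, 82%, 42% and 4%. At 24 h tributyltin had 100%, 94%, 40% and 2%. Unchanged probes made up 3.82%, 5.83% and 1.65% of the simulated calls for tributyltin, pyriproxyfen and bisphenol A at 8 h and 7.81%, 2.5% and 0.833% at 24 h. The simulated errors were independent between probes and arrays, so these shares leave out any structure of slides, scanners or samples.

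Before the data were examined, 1 rule for the probes named in the text and the lists of genes to be tested were fixed. The gene lists could not be run, since they needed gene names or descriptions. The naming rule asked for an informative gene name, past the threshold, with the groups not overlapping, and then for the largest changes. The condition on the name was dropped after the data were seen, because no probe could meet it, and the number of probes was limited to 2 higher and 2 lower per contrast. CUST_94756 and CUST_33104 stand in the text under this rule.

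A position on the time axis was computed per array as its projection on the line from the mean of all 12 arrays at 8 h to that of all 12 at 24 h, then rescaled linearly to 0 and 1 at the 2 control means. Arrays of a time enter the line alike, whatever their exposure. Positions were compared by exact permutation tests in R, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots. Correlations of responses were set against 100 simulated draws of unchanged groups, in which whole-array residuals were shuffled over the 24 places and the chemicals shared simulated controls.

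The alternatives fixed before the data were examined were normexp background correction with an offset of 50 on the mean signals (median signals on arrays without them), quantile normalization, no filter on dim probes, a filter for probes well above background on all 24 arrays, the slide or the replicate number as a block, a fit of only the groups compared, a trended robust spread, array weights, the authors' deposited log2 values, and leaving out each array of the groups compared in turn. Added after the data were seen were the percentile over detected spots, the scanner as a block, the arrays of scanner 1 alone, and the position on the time axis as a covariate. Within slides that held both groups of a comparison, the direction of the called probes was also counted, on arrays that are in the overall fit too.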

Results

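RNA was measured in whole female juveniles of Daphnia magna, a freshwater crustacean used in toxicity testing. The labels gave the animals as 4 days old at 8 h and 5 days old at 24 h after the start of an exposure that began just after the third moult. Juveniles were exposed to tributyltin (an organotin biocide), pyriproxyfen (an insecticide that mimics juvenile hormone), bisphenol A (a plastics monomer) or the solvent alone, here called the control. The labelled concentration of bisphenol A was 10 mg/L and that of each of the other two was 1 mg/L. The unit could not be checked from the files and is in doubt. The series title presents the 3 chemicals as metabolic disruptors that raise lipid storage and asks how the response depends on time. Each of the 8 groups held 3 samples, each hybridised to a separate 1-colour Agilent array, and the number of arrays limits the precision. Between 12286 and 16085 of the 59125 non-control spots of an array (20.8% to 27.2%) were well above background, and 0 spots were saturated. The labels do not say that the samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

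The files pair 0 of the 51424 probes with a gene name, so features are given as probe IDs, without the ending that all IDs share. The 60-base sequences of some probes are printed so that they can be matched to a genome. Normalized signals are log2 values relative to each array's 75th percentile, given as mean ± SD with n = 3 arrays. Log2 differences are given ± the standard error (SE) of limma's moderated test over all 24 arrays, and adjusted p-values are Benjamini-Hochberg values over 13550 tested probes. Where no array of the dimmer group was well above background, the difference is a bound, written as at least N-fold. The bound is the bright group's mean over the dim group's mean of the higher of the array's lowest well-measured signal and the probe's own signal. A probe is called changed where its adjusted p was under 0.05.

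The comparison of control juveniles at 24 h with those at 8 h gave the change over time without a chemical. CUST_58681 (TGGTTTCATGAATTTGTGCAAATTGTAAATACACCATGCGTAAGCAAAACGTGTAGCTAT) rose at least 274-fold (limma adjusted p = 4.15e-11), from a signal that was not well above background on any 8 h control array to 7.96 ± 0.62. CUST_63789 rose at least 829-fold (adjusted p = 0.000281) to 9.56 ± 1.69. CUST_96152 (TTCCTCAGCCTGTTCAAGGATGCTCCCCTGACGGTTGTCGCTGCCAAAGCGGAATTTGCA) fell by 10.04 ± 0.76 on the log2 scale (adjusted p = 7.72e-09), from 9.95 ± 0.17 to -0.09 ± 0.88, and 1 of 3 control arrays at 24 h was still well above background. CUST_58603 fell by 9.88 ± 0.98 (adjusted p = 2.18e-07), also with 1 of 3 arrays well above background at 24 h. In all, 6036 probes changed, 1589 of them higher and 4447 lower at 24 h, and 3207 changed by over 1 on the log2 scale. With the slide as a block 5639 probes changed, and within the slide that held 1 control array of each time 6016 of the 6036 differed in the same direction. The split by direction depended on the settings: with each array's percentile taken over spots detected on all arrays, 2392 probes were higher and 2307 lower, and with no filter on dim probes 20883 were higher and 5771 lower. Without the filter the 37874 dim probes enter. On the control arrays the lowest processed signal was 15.9, 7.69 and 9.51 at 8 h, with 75th percentiles of 80.1, 50.3 and 50.5. At 24 h it was 18.1, 11.9 and 13.2, with percentiles of 79.0, 51.6 and 49.7. After scaling the floor was therefore higher at 24 h, so the higher calls of dim probes are no evidence of a rise. The median log2 difference of all tested probes was -0.30 with the main scaling and 0.03 with the percentile over detected spots. That percentile sets the arrays level over detected spots, so its median near 0 and its near-even split are in part built in.

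At 8 h, the comparison of each chemical with the control gave the early response. With tributyltin, CUST_112711 rose by 3.06 ± 0.63 (adjusted p = 0.0363), from -1.04 ± 1.22 with 1 of 3 control arrays well above background to 2.02 ± 0.43. CUST_132399 rose by 2.66 ± 0.52 (adjusted p = 0.029), from 1.39 ± 0.90 to 4.05 ± 0.41. CUST_77221 fell by 1.43 ± 0.29 (adjusted p = 0.0343) to -0.27 ± 0.18, with 1 of 3 tributyltin arrays well above background, and CUST_140097 fell at least 1.51-fold (adjusted p = 0.0359). In all, 84 probes were higher and 2 lower, or 356 and 175 with array weights, and the 86 had a median absolute log2 difference of 1.41. All 4 probes lay close to the threshold: leaving out any tributyltin array or control replicate 2 ended each call, with an adjusted p of up to 0.311 for CUST_112711 and 0.272 for the other three. With the slide as a block CUST_112711, CUST_132399 and CUST_77221 were not past the threshold (adjusted p = 0.0823, 0.0823 and 0.0776, in ranges of 0.00327 to 0.311, 0.00165 to 0.272 and 0.00352 to 0.272 over their alternatives). The count was 66 with the slide as a block, 43 of them among the 86. It was 1 without control replicate 2, 53 without control replicate 4, 11 without tributyltin replicate 1, 11 without tributyltin replicate 2 and 19 without tributyltin replicate 4.

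Pyriproxyfen at 8 h gave the largest fitted difference from control among the probes named for the 3 chemicals at that time, that of CUST_33104. CUST_33104 (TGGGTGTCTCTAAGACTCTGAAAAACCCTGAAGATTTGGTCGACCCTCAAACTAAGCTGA) rose by 6.66 ± 0.41 on the log2 scale, 101-fold (adjusted p = 8.59e-09), from -0.33 ± 0.11, with 1 of 3 control arrays well above background, to 6.33 ± 0.52. CUST_47871 (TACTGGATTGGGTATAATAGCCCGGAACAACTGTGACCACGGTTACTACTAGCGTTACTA) rose at least 9.42-fold (adjusted p = 4.1e-10) to 3.1 ± 0.6. CUST_127877 (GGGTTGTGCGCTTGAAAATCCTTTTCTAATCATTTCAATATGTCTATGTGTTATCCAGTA) fell by 2.15 ± 0.25 (adjusted p = 0.000134), from 4.59 ± 0.29 to 2.44 ± 0.18. CUST_143597 fell at least 2.95-fold (adjusted p = 0.0194), a call that ended without control replicate 2, control replicate 4 or pyriproxyfen replicate 5 (adjusted p 0.0863 to 0.131) and with the slide as a block (adjusted p = 0.0683, in a range of 0.00421 to 0.261 over its alternatives). The first 3 probes passed the threshold in every alternative that tested them. In all, 35 probes were higher and 39 lower, or 46 and 29 with the percentile over detected spots, and 52 changed with the slide as a block. The count of 74 became 28 without control replicate 2, 42 without control replicate 3, 38 without control replicate 4, 198 without pyriproxyfen replicate 2 and 42 without pyriproxyfen replicate 5.

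Bisphenol A at 8 h raised 9 probes and lowered 0 (limma; 915 probes of either direction had an unadjusted p under 0.05). CUST_108943 (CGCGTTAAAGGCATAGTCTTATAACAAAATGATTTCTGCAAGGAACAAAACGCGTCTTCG) rose by 3.85 ± 0.23, 14.5-fold (adjusted p = 1.74e-08), from 1.67 ± 0.36 to 5.53 ± 0.22. CUST_71115 (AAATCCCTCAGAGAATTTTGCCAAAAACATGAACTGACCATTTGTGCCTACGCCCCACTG) rose by 3.63 ± 0.35, 12.4-fold (adjusted p = 2.16e-05), from 0.92 ± 0.34 to 4.55 ± 0.14. Both passed the threshold in every alternative that tested them. At 24 h 6 of the 9 probes were past the threshold with bisphenol A, with a median log2 difference of 1.13 over the 9, against 2.21 at 8 h. The count was 9 with the slide as a block and 16 without bisphenol A replicate 1, of which 9 were higher and 7 lower.

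At 24 h tributyltin raised CUST_27039 by 4.84 ± 0.96 (adjusted p = 0.031), from -0.11 ± 2.16, with 1 of 3 control arrays well above background, to 4.74 ± 0.81. CUST_113154 rose by 4.77 ± 0.80 (adjusted p = 0.0142), from -0.92 ± 1.57, again with 1 of 3 control arrays well above background, to 3.85 ± 1.22. CUST_33104, raised by pyriproxyfen, fell at least 3.09-fold with tributyltin (adjusted p = 0.0142), and CUST_129324 fell by 2.33 ± 0.47 (adjusted p = 0.0313) to 1.45 ± 0.65. In all, 79 probes were higher and 4 lower, or 20 and 5 with the percentile over detected spots. Tributyltin and control arrays at 24 h shared no slide. With the replicate number as a block 21 probes changed, and with the slide as a block 34 did. CUST_27039 and CUST_129324 were not past the threshold with the slide as a block (adjusted p = 0.0638 and 0.160, in ranges of 0.00676 to 0.351 and 0.0233 to 0.317 over their alternatives), nor was CUST_27039 with the percentile over detected spots (adjusted p = 0.0611). All 4 calls ended without tributyltin replicate 2 or control replicate 3, the first 2 also without control replicate 2, and that of CUST_129324 also without control replicate 2, control replicate 4 or tributyltin replicate 1, at adjusted p between 0.0555 and 0.155. The count of 83 became 15 without control replicate 2, 6 without control replicate 3, 0 without tributyltin replicate 2 (limma; 1052 at an unadjusted p under 0.05) and 209 without tributyltin replicate 4.

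Pyriproxyfen at 24 h raised CUST_58596 at least 18.6-fold (adjusted p = 0.017) to 4.51 ± 3.35. CUST_113154 rose by 5.50 ± 0.80 (adjusted p = 0.00115) to 4.57 ± 1.90, with 1 of 3 control arrays well above background. CUST_101160 fell at least 7.92-fold (adjusted p = 0.0305) and CUST_2076 fell by 2.34 ± 0.52 (adjusted p = 0.0192), from 4.37 ± 0.35 to 2.02 ± 0.88. In all, 316 probes were higher and 32 lower, and 381 changed with the slide as a block and 212 with the replicate number as a block. Of the 4 probes, CUST_113154 kept its call when any 1 array was left out, but not with only the groups compared in the fit (limma adjusted p = 0.295). The other three lost it without control replicate 3 or pyriproxyfen replicate 4, CUST_58596 and CUST_101160 also without pyriproxyfen replicate 2 and CUST_101160 also without control replicate 2, at adjusted p between 0.0718 and 0.163. The count of 348 became 101 without control replicate 3, 170 without pyriproxyfen replicate 2, 82 without pyriproxyfen replicate 4 and 622 without pyriproxyfen replicate 5.

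With bisphenol A at 24 h, CUST_58596 (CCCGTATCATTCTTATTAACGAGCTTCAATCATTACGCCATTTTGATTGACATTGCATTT) rose at least 78.8-fold (adjusted p = 0.00147) to 6.59 ± 0.38, and CUST_35686 rose by 6.81 ± 1.70 (adjusted p = 0.0296), from -0.20 ± 2.14, with 1 of 3 control arrays well above background, to 6.61 ± 0.26. CUST_101160 fell at least 6.93-fold (adjusted p = 0.0176). CUST_76717 fell at least 2.56-fold (adjusted p = 0.0374) from 1.48 ± 2.29, with 2 of 3 control arrays well above background. The call of CUST_76717 held in 6 of its 19 alternatives and not with the slide as a block (adjusted p = 0.122, in a range of 0.00329 to 0.370). In all, 471 probes were higher and 65 lower, 445 of them by over 1 on the log2 scale, and 681 changed with the slide as a block. CUST_58596 kept its call when any 1 array was left out. The calls of the other three ended without control replicate 3, bisphenol A replicate 1 or bisphenol A replicate 2, those of CUST_35686 and CUST_76717 also without bisphenol A replicate 4, those of CUST_35686 and CUST_101160 also without control replicate 2 and that of CUST_76717 also without control replicate 4, at adjusted p between 0.0519 and 0.212. The count of 536 became 153 without control replicate 3, 204 without bisphenol A replicate 1 and 229 without bisphenol A replicate 4.

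**Figure D1:**
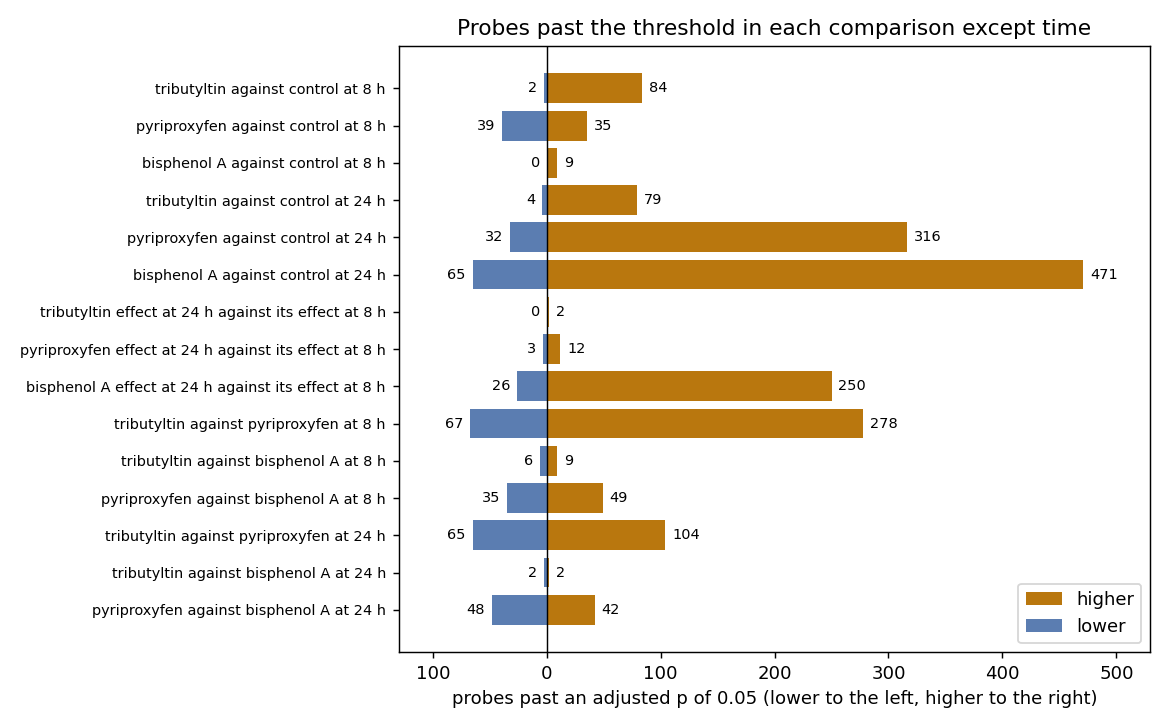
Number of probes with an adjusted p under 0.05 in each comparison except that over time, with probes higher in the first-named group to the right of 0 and lower ones to the left. At 24 h bisphenol A had 471 higher and 65 lower probes, against 9 and 0 at 8 h.

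Whether a chemical's difference from control changed between 8 h and 24 h was tested as an interaction. For bisphenol A 276 probes changed, 250 of them upward, or 147 upward and 38 downward with the percentile over detected spots and 243 in all with the slide as a block. CUST_58596 stood at 6.55 ± 0.53 with bisphenol A and 7.28 ± 0.14 in control at 8 h, and at 6.59 ± 0.38 with bisphenol A against a control that was not well above background at 24 h (interaction adjusted p = 0.0173). For pyriproxyfen 15 probes changed, 12 of them upward, or 4 upward and 3 downward with the percentile over detected spots, 5 upward and 13 downward with no filter on dim probes and 13 in all with the slide as a block. CUST_33104 had a smaller difference from control at 24 h, at 3.20 ± 0.41, than at 8 h, at 6.66 ± 0.41 (interaction -3.47 ± 0.58, adjusted p = 0.0188). For tributyltin 2 probes changed, both upward, and with the percentile over detected spots 0 did (limma; 885 at an unadjusted p under 0.05). All 3 counts moved by over 1.5 times when single arrays were left out, and those arrays are listed with the flagged interaction results.

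The chemicals were also compared with each other at the same time. The labelled concentration of bisphenol A was 10 times that of the other two, so differences from it are differences at unequal concentrations. At 8 h tributyltin and pyriproxyfen differed at 345 probes, 278 higher and 67 lower with tributyltin, and 379 with the slide as a block. CUST_33104 was at least 97.9-fold lower with tributyltin than with pyriproxyfen (adjusted p = 3.34e-10), and CUST_94756 (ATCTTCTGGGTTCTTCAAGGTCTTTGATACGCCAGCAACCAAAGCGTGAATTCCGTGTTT) at least 15.4-fold lower (adjusted p = 7.94e-09). CUST_36222 was at least 3.73-fold higher with tributyltin (adjusted p = 7.83e-09), and CUST_52811 was higher by 4.23 ± 0.99 (adjusted p = 0.0224), a call that ended without any single pyriproxyfen array, tributyltin replicate 1 or tributyltin replicate 2 (adjusted p 0.0577 to 0.124) and with the slide as a block (adjusted p = 0.0833, in a range of 0.00269 to 0.124 over its alternatives). The count became 200 without pyriproxyfen replicate 2 and 195 without tributyltin replicate 1.

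Pyriproxyfen and bisphenol A differed at 84 probes at 8 h, 49 higher and 35 lower with pyriproxyfen, and at 56 with the slide as a block. CUST_33104 was at least 76.4-fold higher with pyriproxyfen (adjusted p = 1.32e-09) and CUST_94756 at least 12-fold higher (adjusted p = 2.59e-08), while the log2 difference was -4.22 ± 0.23 for CUST_108943 (adjusted p = 1.32e-09) and -3.95 ± 0.35 for CUST_71115 (adjusted p = 1.87e-06). Tributyltin and bisphenol A differed at 15 probes at 8 h, 9 higher and 6 lower with tributyltin, and at 15 with the slide as a block. CUST_41163 was higher with tributyltin by 2.97 ± 0.38 (adjusted p = 0.00151) and CUST_118887 by 2.03 ± 0.31 (adjusted p = 0.00661), with 1 of 3 bisphenol A arrays well above background, a call that ended without bisphenol A replicate 2 or tributyltin replicate 4 (adjusted p 0.0615 and 0.0707). CUST_108943 was 8.34-fold lower (adjusted p = 9.07e-07) and CUST_71115 7.37-fold lower (adjusted p = 0.000764). With only the groups compared in the fit the call of CUST_71115 ended (limma adjusted p = 0.179), as did that of CUST_118887. The count of 84 became 55 without bisphenol A replicate 4, 49 without pyriproxyfen replicate 4 and 51 without pyriproxyfen replicate 5. The count of 15 became 4 without bisphenol A replicate 2, 8 without bisphenol A replicate 4, and 6, 9 and 7 without tributyltin replicates 1, 2 and 4.

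At 24 h tributyltin and pyriproxyfen differed at 169 probes, 104 higher and 65 lower with tributyltin, or 61 and 98 with the percentile over detected spots, and at 123 with the slide as a block. CUST_33104 was at least 28.4-fold lower with tributyltin (adjusted p = 2.43e-07) and the log2 difference of CUST_129324 was -4.59 ± 0.47 (adjusted p = 1.33e-05). CUST_119027 was at least 2.43-fold higher (adjusted p = 7.84e-06). CUST_52811 was higher by 4.16 ± 0.99 (adjusted p = 0.0427), with 2 of 3 pyriproxyfen arrays well above background, a call that ended without pyriproxyfen replicates 4 or 5 or tributyltin replicates 1 or 2 (adjusted p 0.0534 to 0.268). That call held in 5 of its 19 alternatives, with an adjusted p of 0.142 with the slide as a block and 0.0554 with the percentile over detected spots, in a range of 0.0281 to 0.459. The count became 101, 95 and 257 without pyriproxyfen replicates 2, 4 and 5, and 82 and 85 without tributyltin replicates 1 and 2.

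Pyriproxyfen and bisphenol A differed at 90 probes at 24 h, 42 higher and 48 lower with pyriproxyfen, and at 95 with the slide as a block. CUST_90121 was higher with pyriproxyfen by 5.78 ± 0.60 (adjusted p = 2.75e-05), with 1 of 3 bisphenol A arrays well above background, and CUST_101289 by 5.73 ± 0.82 (adjusted p = 0.001). CUST_70866 had a log2 difference of -2.82 ± 0.24 (adjusted p = 4.53e-06) and CUST_149101 was at least 2.27-fold lower (adjusted p = 0.0343), with 2 of 3 bisphenol A arrays well above background, the latter not past the threshold without bisphenol A replicates 2 or 4 or pyriproxyfen replicates 4 or 5 (adjusted p 0.0846 to 0.215). Tributyltin and bisphenol A differed at 4 probes, or 28 with the slide as a block. CUST_42410 was at least 1.3-fold higher with tributyltin (adjusted p = 0.00789, in a range of 0.00264 to 0.299 over its alternatives, and not past the threshold with normexp background correction, with only the groups compared in the fit or on scanner 1 alone), CUST_127877 was 3.35-fold higher (adjusted p = 0.00789), CUST_33104 at least 4.02-fold lower (adjusted p = 0.00789) and CUST_94129 had a log2 difference of -5.02 ± 0.85 (adjusted p = 0.041). Leaving out any 1 of the 6 arrays ended the call of CUST_94129 (adjusted p 0.0629 to 0.146), and leaving out bisphenol A replicate 1 or tributyltin replicate 2 ended that of CUST_33104 (0.0537 and 0.0768). With only the groups compared in the fit, the calls of the other probes named for these pairs ended too. The limma adjusted p was then 0.131 for CUST_90121, 0.0791 for CUST_101289, 0.0624 for CUST_70866 and 0.373 for CUST_127877. The count of 90 became 40 without bisphenol A replicate 2, 45 without bisphenol A replicate 4 and 45 without pyriproxyfen replicate 2, and the count of 4 became 10 without bisphenol A replicate 4, 2 without tributyltin replicate 2 and 12 without tributyltin replicate 4.

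**Figure D2:**
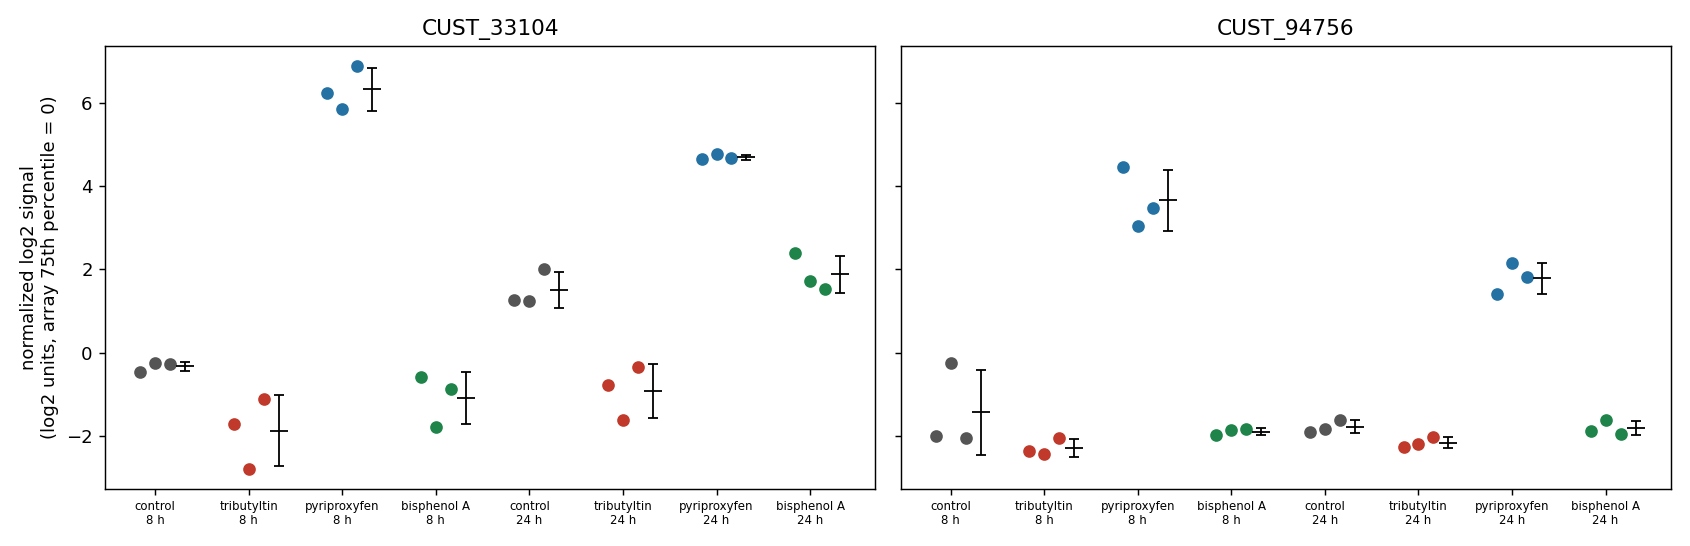
Normalized log2 signal of CUST_33104 and CUST_94756 on each of the 24 arrays, by group, with circles for arrays and black bars for the mean ± SD (n = 3). With pyriproxyfen CUST_33104 averaged 6.33 at 8 h and 4.70 at 24 h, above every other group at each time, and CUST_94756 was well above background on 3 of 3 pyriproxyfen arrays at each time and on 0 of 3 control arrays.

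The overlap of the responses was measured by correlating log2 differences from control across the 13550 probes, which are not independent replicates. The chemicals were compared with the same control arrays, so unchanged groups also give a correlation above 0, and 100 simulations of such groups gave that value. The simulations pooled the residuals of both times, so their controls had the same spread at each time. The real control arrays correlated with each other at 0.944 to 0.959 at 24 h and at 0.968 to 0.986 at 8 h. The simulated values may therefore understate the part of shared controls at 24 h and overstate it at 8 h. At 24 h the correlation was 0.83 ± 0.113 (jackknife SE over arrays) between pyriproxyfen and bisphenol A (simulated mean 0.51, upper limit of the central 95% of draws 0.78), 0.80 ± 0.189 between tributyltin and bisphenol A (0.50 and 0.81) and 0.73 ± 0.193 between tributyltin and pyriproxyfen (0.52 and 0.80), so in the fit of all arrays it passed its limit for pyriproxyfen and bisphenol A alone, and without pyriproxyfen replicate 4 it did not, at 0.716. The covariance, for which no jackknife SE was computed, was 0.443 against a simulated 0.0922 for pyriproxyfen and bisphenol A, 0.332 against 0.0898 for tributyltin and bisphenol A, and 0.253 against 0.094 for tributyltin and pyriproxyfen. Both pyriproxyfen and bisphenol A raised 227 probes at 24 h, where independent lists would share 10.98, and lowered 4, where they would share 0.154. Tributyltin shared 43 raised probes with bisphenol A (2.75 for independent lists) and 38 with pyriproxyfen (1.84). Called probes went in opposite directions at 2 probes for pyriproxyfen and bisphenol A, 4 for tributyltin and pyriproxyfen and 0 for tributyltin and bisphenol A. Independent lists leave the shared controls out of account. Simulated unchanged groups with shared controls had 0 raised probes in common in each of 100 draws, but these groups hold no effect. That value therefore cannot show how far shared controls add to the probes that 2 lists share. The 3 control arrays of a time were not split between the chemicals of a pair, so part of the likeness may come from the shared controls. The correlation became 0.607 for tributyltin and bisphenol A without tributyltin replicate 2.

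At 8 h the correlations were 0.34 ± 0.207 between tributyltin and pyriproxyfen, 0.65 ± 0.249 between tributyltin and bisphenol A and 0.32 ± 0.254 between pyriproxyfen and bisphenol A, each below the upper limit of its simulation (0.798, 0.766 and 0.797). Between 8 h and 24 h the correlation of a chemical's differences was -0.09 for tributyltin, 0.02 for pyriproxyfen and -0.44 for bisphenol A, for which unchanged groups gave a range of -0.52 to 0.46. Pyriproxyfen raised 18 and lowered 8 probes at both times, where independent lists would share 0.816 and 0.0921. Tributyltin raised 12 at both times (0.49 for independent lists).

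Each array was also placed on the axis from the mean of all 12 arrays at 8 h to that of all 12 at 24 h, rescaled with the mean of the control arrays at 8 h set to 0 and at 24 h set to 1. At 24 h the bisphenol A arrays stood at 0.81 ± 0.034 (SD, n = 3), the pyriproxyfen arrays at 0.86 ± 0.17 and the tributyltin arrays at 0.94 ± 0.075, and each of the 3 control arrays stood between 0.99 and 1.01. The 9 exposed arrays at 24 h lay 0.131 below the 3 control arrays (two-sided exact permutation p = 0.0455, Benjamini-Hochberg adjusted p = 0.267 over 8 tests), which did not pass the threshold after adjustment. For 3 arrays against 3 the smallest p that an exact permutation test can give is 0.1. At 8 h the 9 exposed arrays differed from control by 0.00499 (exact permutation p = 0.882). Bisphenol A replicate 1 stood at 0.135 there, and every other array at 8 h lay between -0.0531 and 0.0458.

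**Figure D3:**
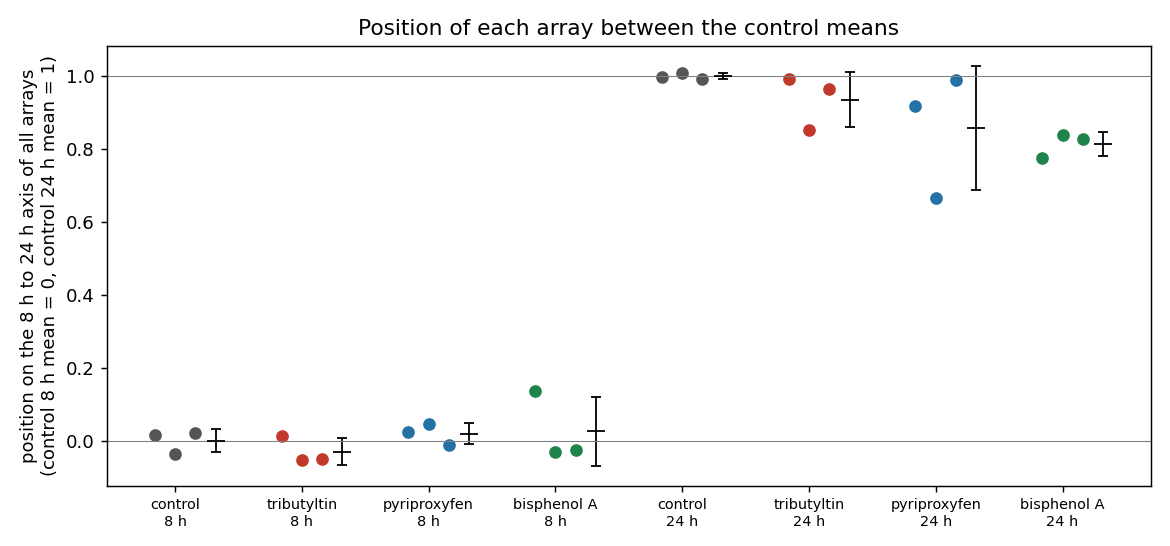
Position of each of the 24 arrays on the axis from all arrays at 8 h to all arrays at 24 h, rescaled to 0 at the control mean at 8 h and 1 at the control mean at 24 h, by group, with circles for arrays and black bars for the mean ± SD (n = 3). At 24 h the bisphenol A arrays lay between 0.775 and 0.838 and the pyriproxyfen arrays between 0.666 and 0.99.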

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

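The tests of the scanners, of a slower change with pyriproxyfen and tributyltin, of the splits with balanced scanners, of the scaling and slide for tributyltin at 24 h, and of CUST_33104 in the passages that follow were chosen after their results were seen, as were the alternatives with the percentile over detected spots, the scanners and the position as a covariate.

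The response to a chemical differed between 8 h and 24 h, by limma's interaction test, at 276 probes for bisphenol A, 15 for pyriproxyfen and 2 for tributyltin. For bisphenol A the interaction was 9.92 on the log2 scale for CUST_59210 (adjusted p = 0.0254), 8.41 for CUST_58596 (adjusted p = 0.0173), -6.56 for CUST_101160 (adjusted p = 0.023) and -5.98 for CUST_76717 (adjusted p = 0.0251). In each of these 4 at least 1 of the 4 groups was not well above background on any array, so the fitted sizes are no bounds. For pyriproxyfen it was 5.24 for CUST_90121 (adjusted p = 0.0182), 3.24 for CUST_54553 (adjusted p = 0.0182), -3.47 for CUST_33104 (adjusted p = 0.0188) and -2.52 for CUST_47871 (adjusted p = 0.0083), and all but CUST_33104 had a group not well above background on any array. For tributyltin it was 1.79 for CUST_123521 (adjusted p = 0.0384), measured on all arrays of the 4 groups, and the other called probe, CUST_123517, which was added after its value was seen, holds the same sequence. The call of CUST_123521 ended without control replicates 2 or 4 at 8 h, control replicates 2 or 3 at 24 h, tributyltin replicates 1 or 4 at 8 h or tributyltin replicates 1 or 2 at 24 h (adjusted p 0.0551 to 0.175).

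The count of 276 became 87, 112 and 119 without control replicates 2, 3 and 4 at 8 h, 43 without control replicate 3 at 24 h, 76 and 94 without bisphenol A replicates 2 and 4 at 8 h, and 64, 182 and 105 without bisphenol A replicates 1, 2 and 4 at 24 h. The count of 15 became 5, 6 and 9 without control replicates 2, 3 and 4 at 8 h, 31, 8 and 42 without control replicates 2, 3 and 4 at 24 h, 23, 8 and 6 without pyriproxyfen replicates 2, 4 and 5 at 8 h, and 238 without pyriproxyfen replicate 5 at 24 h. The count of 2 became 29 without control replicate 4 at 24 h and 0 without the 8 arrays that ended the call of CUST_123521, each left out in turn (limma; 950 to 1970 probes at an unadjusted p under 0.05).

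Single-array calls among the pyriproxyfen interactions ended as follows. CUST_90121 lost its call without control replicate 2 or pyriproxyfen replicate 5 at 8 h (adjusted p 0.0597 and 0.0609), CUST_33104 without those or control replicate 3 at 8 h (0.0547 to 0.0738), and CUST_54553 without those 3 or control replicate 3 at 24 h (0.0547 to 0.0648), while CUST_47871 kept its call. Among the bisphenol A interactions, CUST_58596 lost its call without control replicate 3 at 24 h, bisphenol A replicate 2 at 8 h or bisphenol A replicate 1 at 24 h (0.0546 to 0.0642). CUST_59210 lost it without 6 of the 12 arrays (control replicates 2 and 4 at 8 h and 3 at 24 h, bisphenol A replicates 2 and 4 at 8 h and 4 at 24 h), CUST_101160 without 5 (control replicate 2 at 8 h and 3 at 24 h, bisphenol A replicates 2 and 4 at 8 h and 1 at 24 h) and CUST_76717 without 7 (control replicates 2 and 3 at 8 h and 3 and 4 at 24 h, bisphenol A replicate 4 at 8 h and 1 and 4 at 24 h), at adjusted p between 0.0512 and 0.0808. With the slide as a block CUST_76717 was not past the threshold either (adjusted p = 0.0638, in a range of 0.0139 to 0.191 over its alternatives), nor was CUST_123521 for tributyltin (adjusted p = 0.221, in a range of 0.0132 to 0.391).

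Other splits of the 12 arrays of each interaction were counted over 100 draws, the real split included. For bisphenol A 1 of 100 splits gave as many probes as the real 276 (highest other 189), a share under 0.05. The splits mixed exposed and control arrays within each time. They therefore stand for no response at either time, not for an equal response at both, and real differences between the groups widen their spread. Chance is not excluded by them for a change of the response with time. For pyriproxyfen 3 of 100 gave 15 or more and for tributyltin 3 of 100 gave 2 or more, also shares under 0.05. The highest other splits, with 220 probes for pyriproxyfen and 102 for tributyltin, called several times the real count. A structure of the samples beyond the groups may lie behind this, which was not tested. The tributyltin count rests on 1 sequence and was 0 with the slide as a block, so for it and for pyriproxyfen the share is weak evidence. Among splits with as many scanner 2 arrays on each side as the real one, 1 of 72 gave 276 or more for bisphenol A (highest other 189), 4 of 100 gave 15 or more for pyriproxyfen (280) and 4 of 72 gave 2 or more for tributyltin (335), which is not under 0.05. On scanner 1 alone the bisphenol A count was 27, and no call was left for pyriproxyfen or tributyltin. For the comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. Against control the real counts and the highest of the other splits were 86 and 0 for tributyltin at 8 h, 74 and 20 for pyriproxyfen at 8 h, 9 and 0 for bisphenol A at 8 h, 83 and 0 for tributyltin at 24 h, 348 and 20 for pyriproxyfen at 24 h, 536 and 2 for bisphenol A at 24 h, and 6036 and 0 for time. Between chemicals they were 345 and 0 for tributyltin and pyriproxyfen at 8 h, 169 and 95 for the same pair at 24 h, 4 and 1 for tributyltin and bisphenol A at 24 h, and 90 and 37 for pyriproxyfen and bisphenol A at 24 h. For pyriproxyfen and bisphenol A at 8 h they were 84 and 115, and for tributyltin and bisphenol A at 8 h 15 and 145, each with 2 of 10 splits as large as the real one. The split with 145 set tributyltin replicates 1 and 2 and bisphenol A replicate 1 against the rest and had both arrays of scanner 2 on 1 side. A structure of the samples may lie behind it, which was not tested. For tributyltin against control at 8 h a split with both arrays of scanner 2 on 1 side gave 0. The real count of 15 was 15 with the slide as a block and 3 on scanner 1 alone.

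At 24 h the mean position of each exposed group lay nearer to the 8 h arrays than the control mean did, at 0.81 of the way for bisphenol A, of which every array lay below the controls, while tributyltin replicate 1 lay within the control range. For bisphenol A a difference between scanners is argued against, since on scanner 1 alone the control mean exceeded the bisphenol A mean by 0.198. Percentile scaling is argued against likewise, since with the percentile over detected spots the bisphenol A gap was 0.984 of its main value. The scanners were not tested for the other chemicals and stay open there. Pyriproxyfen arrays stood at 0.918 and 0.99 on scanner 1 and 0.666 on scanner 2, and tributyltin arrays at 0.993 and 0.852 on scanner 1 and 0.964 on scanner 2. RNA of 8 h animals mixed into the bisphenol A samples stays open: its share came out at 0.312 ± 0.175 (SD, n = 3 arrays) from 335 probes that rose over 16-fold with time and at 0.0273 ± 0.0346 from 110 that fell as much, a difference of 0.284, with the fold limit set when the test was written. The share was not computed for single control arrays, so the spread of the controls alone may give such a difference. In a family of 14 probes that rose with time, the median signal was 3.71, 5.88 and 5.90 on the control arrays at 24 h. A slower change may contribute with bisphenol A and pyriproxyfen and stays open there. Of their calls, 74.1% and 57.8% (48.5% to 65% for pyriproxyfen without 1 array) lay against the time change in the arrays of the other chemicals. That time change was centred on its median over the tested probes, while the differences from control were not. Shares without the centring were not computed. Over 90% or under 60% would have decided it, for pyriproxyfen and tributyltin also without any 1 array that leaves a call. For tributyltin 41% (32.4% to 53.3%, with no call left without replicate 2) argues against it, on the centred scale, as the source of most calls. The difference of position itself did not pass the threshold after adjustment (exact permutation test, adjusted p = 0.267).

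With tributyltin at 24 h 79 of 83 called probes were higher. The share of the 83 calls still made was 0.289 with the percentile over detected spots, 0.337 with the slide as a block and 0.458 with the position on the time axis as a covariate. The median absolute log2 difference of the 83 was 1.48 (median SE 0.289) in the main fit and 1.32 (0.281), 1.54 (0.336) and 1.45 (0.304) in these, with 83 of 83 in the same direction each time. The median difference fell by less than 1 SE or rose, the median SE rose in the last 2, and which of these ended a call was not tested. A condition that the median must fall by over 1 SE was added after these values were seen. None of the scaling, the position and the slide met it, but most of the 83 calls ended with each. Each could therefore be the cause of part of the calls and cannot be told apart from the chemical here. Tributyltin and control arrays did not share a slide.

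CUST_33104 was higher with pyriproxyfen at 8 h by 6.66 on the log2 scale. A difference between slides is argued against, since within the slide that held both groups the difference was 6.61, and so is a fault of its spot, since at 24 h the lowest pyriproxyfen array, of 3 on 3 slides, exceeded the highest other array by 2.26. Cross-hybridisation of this probe alone stays open. The other tested probe that shares 10 residues with it in translation, CUST_94756, had a fitted difference of 5.10 (limma adjusted p = 1.41e-07; at least 13.6-fold, control not well above background), but it holds them on the opposite strand, so the 2 probes as printed would bind RNA of opposite strands. A response of a transcript to pyriproxyfen also stays open, and cross-hybridisation of both probes to other sequences was not tested.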

How the results depend on the processing

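The settings with the percentile over detected spots, the scanner as a block, the arrays of scanner 1 alone and the position on the time axis as a covariate were chosen after the data were seen; the others were fixed before. Counts are of probes at an adjusted p under 0.05 in limma. With between 20.8% and 27.2% of spots well above background, a probe dim in a group has only a bound there, and 37874 probes were untested. Counts not named under a setting stayed within 1.5 times the main count. The causes of the moves were not tested, except where fewer probes or fewer arrays entered by construction. The gene lists, and with them the correlation between genes, the mean over a gene's probes and the other alternatives planned for them, were not run, because no probe carries a gene name.

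With normexp background correction the count was 168 for tributyltin at 8 h, 45 for pyriproxyfen at 8 h, 0 for the tributyltin interaction (874 at an unadjusted p under 0.05), 124 for the bisphenol A interaction, 53 for pyriproxyfen against bisphenol A at 8 h, 86 for tributyltin against pyriproxyfen at 24 h and 41 for pyriproxyfen against bisphenol A at 24 h. Its higher and lower calls were 34 and 11 for pyriproxyfen at 8 h, 39 and 47 for tributyltin against pyriproxyfen at 24 h and 27 and 14 for pyriproxyfen against bisphenol A at 24 h. With quantile normalization the tributyltin interaction had 0 (987 unadjusted) and the pyriproxyfen interaction 36. With the authors' value table these were 0 (1010 unadjusted) and 39, and pyriproxyfen at 8 h had 43 higher and 31 lower probes. With the percentile over detected spots tributyltin at 24 h had 25, its interaction 0 (885 unadjusted) and the pyriproxyfen interaction 7. That scaling moved the median log2 difference of all tested probes from 0.15 to -0.01 for tributyltin at 24 h, from 0.12 to -0.01 for tributyltin against pyriproxyfen at 24 h, and from 0.21 and 0.15 to 0.00 for the interactions of tributyltin and bisphenol A. A median near 0 is in part built into that scaling.

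Of 59 values of named probes, 28 were not past the threshold with only the groups compared in the fit, 25 on scanner 1 alone, 22 with the position covariate (2 of them reversed), 20 with no filter on dim probes, 14 with normexp, 11 with the slide block and 10 with the replicate block. The filter for probes well above background on all 24 arrays left 8 of the 59 to be tested, and these 8 stayed past the threshold. Each other setting lost at most 3. Without the filter the count was 34 for tributyltin at 8 h, 22 for tributyltin at 24 h, 163 for pyriproxyfen at 24 h, 307 for bisphenol A at 24 h, 26654 for time, 1 for the tributyltin interaction and 70 for the bisphenol A interaction. The count for time took in dim probes, for which the floor after scaling was higher on the control arrays at 24 h than at 8 h. With only the 7978 probes well above background on all 24 arrays it was 47 for pyriproxyfen at 8 h, 3 for bisphenol A at 8 h, 112 for pyriproxyfen at 24 h, 166 for bisphenol A at 24 h, 3382 for time, 3 and 30 for the interactions of pyriproxyfen and bisphenol A, 215 for tributyltin against pyriproxyfen at 8 h, 47 for pyriproxyfen against bisphenol A at 8 h, and at 24 h 108 for tributyltin against pyriproxyfen, 16 for tributyltin against bisphenol A and 50 for pyriproxyfen against bisphenol A.

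With the slide block tributyltin at 24 h had 34, its interaction 0 (1050 unadjusted) and tributyltin against bisphenol A at 24 h 28. With the scanner block tributyltin had 141 at 8 h and 163 at 24 h, the bisphenol A interaction 453 and tributyltin against bisphenol A at 24 h 37. On the 17 arrays of scanner 1 the count was 28 for tributyltin, 31 for pyriproxyfen and 3 for bisphenol A at 8 h, 64 for pyriproxyfen and 315 for bisphenol A at 24 h, 0 for the interactions of tributyltin (1024 unadjusted) and pyriproxyfen (995 unadjusted) and 27 for that of bisphenol A. Between chemicals it was 3 for tributyltin against bisphenol A and 44 for pyriproxyfen against bisphenol A at 8 h, and at 24 h 95 for tributyltin against pyriproxyfen, 7 for tributyltin against bisphenol A and 41 for pyriproxyfen against bisphenol A.

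With only the groups compared in the fit, which leaves fewer arrays to estimate the spread, the count was 0 for tributyltin at 8 h (1591 unadjusted), 9 for pyriproxyfen and 5 for bisphenol A at 8 h, 0 for tributyltin at 24 h (1443 unadjusted), 11 for pyriproxyfen at 24 h, and 0 (1305 unadjusted), 3 and 595 for the interactions of tributyltin, pyriproxyfen and bisphenol A. Between chemicals it was 139 for tributyltin against pyriproxyfen, 2 for tributyltin against bisphenol A and 14 for pyriproxyfen against bisphenol A at 8 h, and 22, 0 (1085 unadjusted) and 13 for the same pairs at 24 h. With a trended robust spread tributyltin against bisphenol A at 24 h had 12. With array weights the count was 531 for tributyltin (356 higher, 175 lower), 777 for pyriproxyfen and 15 for bisphenol A (12 and 3) at 8 h, 714 for pyriproxyfen at 24 h, 25, 212 and 658 for the interactions of tributyltin, pyriproxyfen and bisphenol A, and at 24 h 355 for tributyltin against pyriproxyfen, 19 for tributyltin against bisphenol A and 423 for pyriproxyfen against bisphenol A.

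With the replicate block the count was 21 for tributyltin and 212 for pyriproxyfen at 24 h, 0 (1720 unadjusted) and 40 for the interactions of tributyltin and pyriproxyfen, 25 for tributyltin against bisphenol A at 24 h and 137 for pyriproxyfen against bisphenol A at 24 h. The replicate numbers were not taken to pair the samples, since the rule asked for r over 0.1 in every pair: over 64 pairs of arrays with the same number, deviations from the group means correlated at a median r of 0.183 (range -0.539 to 0.568, 41 pairs over 0.1). The median r was -0.0661 for different numbers and 0.203 for the same number on the same scanner, and 14 of 24 arrays correlated best with their own number, so some likeness by number remains. The median r was 0.123 on the same scanner and -0.132 on different scanners.

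With the position on the time axis as a covariate, which is built from the difference between the times and is nearly collinear with it, the count was 41 for tributyltin, 59 for pyriproxyfen and 41 for bisphenol A at 24 h, 0 for time (699 unadjusted), and 4 and 2 for the interactions of pyriproxyfen and bisphenol A. In the time comparison CUST_63789 reversed to -11.65 and CUST_58603 to 3.06 on the log2 scale, neither past the threshold.

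The correlation of responses over probes past the threshold in either comparison was -0.0883 for tributyltin and pyriproxyfen at 8 h and 0.0845 for tributyltin and bisphenol A at 8 h. With the simulated covariance of shared controls subtracted it was -0.134 for tributyltin and pyriproxyfen, 0.261 for tributyltin and bisphenol A and -0.151 for pyriproxyfen and bisphenol A at 8 h, and 0.457, 0.582 and 0.66 for the same pairs at 24 h. The simulation gave both times the same spread, so it may subtract too much at 8 h and too little at 24 h.

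Leaving out 1 array at a time moved 71 of 114 counts by over 1.5 times. The lowest and highest counts were 1 and 74 for tributyltin, 28 and 198 for pyriproxyfen and 7 and 16 for bisphenol A at 8 h, 0 and 209, 82 and 622, and 153 and 583 for them at 24 h, 5084 and 5597 for time, and 0 and 29, 5 and 238, and 43 and 337 for their interactions. Between chemicals they were 195 and 288 for tributyltin against pyriproxyfen, 4 and 12 for tributyltin against bisphenol A and 49 and 67 for pyriproxyfen against bisphenol A at 8 h, and 82 and 257, 2 and 12, and 40 and 97 at 24 h. The correlations ranged from 0.246 to 0.462 for tributyltin and pyriproxyfen, 0.46 to 0.706 for tributyltin and bisphenol A and 0.169 to 0.419 for pyriproxyfen and bisphenol A at 8 h, from 0.544 to 0.798, 0.607 to 0.844 and 0.716 to 0.867 at 24 h, and between the times from -0.185 to 0.0747 for tributyltin, -0.065 to 0.155 for pyriproxyfen and -0.459 to -0.342 for bisphenol A. Of 408 values of named probes without 1 array, 289 kept their direction and side of the threshold and 119 kept only their direction.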

Other observations

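The tests in the passages that follow were all chosen after the results were seen, and the sequence families were found and chosen in these data.

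Of 13183 tested probes searched, 1419 fell into 521 families, in which each member shares 8 residues in translation with at least 1 other member but not always with all. The mean SD of the change from 8 h to 24 h within a family was 0.346 on the log2 scale, against a mean of 1.12 and a lowest value of 0.968 in 10000 random groupings of the same sizes, 0 of which were as low. Families were joined over both strands, and some hold members on opposite strands. With probes joined only on the same strand, 1185 probes in 439 families had a mean SD of 0.290, against a lowest value of 1.01 in 10000 random groupings. A candidate explanation is that related transcripts respond alike, and part of the likeness may be built in, because members that share sequence on a strand can bind the same RNA. The largest families, of 51, 50 and 36 probes, had median time changes of -0.04, -0.24 and -0.359, so a small spread within a family need not be a response. In the family of 14 probes that includes CUST_1065 (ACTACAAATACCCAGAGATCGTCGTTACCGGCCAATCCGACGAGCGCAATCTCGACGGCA), all 14 rose with time, with a median of 7.04. The most common run of 8 residues of CUST_1065 occurred in 5 of the 14. In juveniles exposed for 24 h the median differences from control were -2.60 for bisphenol A, -2.29 for pyriproxyfen and -1.44 for tributyltin. They were taken against the same 3 control arrays and over probes of which some may bind the same RNA, so their agreement was not tested. None of these passed the threshold (limma; 4, 2 and 0 probes at an unadjusted p under 0.05), and the medians kept their signs with the percentile over detected spots and with quantile normalization. The family's median signal was 6.32 on the array of bisphenol A replicate 1 at 8 h, against -1.19 and -0.43 on the other arrays of its group and -1.28 to -1.10 on control arrays at 8 h. At 24 h it was 3.71, 5.88 and 5.90 on the control arrays, 3.50, 1.97 and 2.77 on those of bisphenol A, 4.92, 0.57 and 2.80 on those of pyriproxyfen and 5.26, 1.5 and 5.17 on those of tributyltin, so 6 of the 9 exposed arrays lay below the controls and 3 within their range.

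The 9 probes raised by bisphenol A at 8 h had a median log2 difference of 2.21 with it, 0.75 with tributyltin, where 9 were higher, and 0.61 with pyriproxyfen, where 5 were higher and 4 lower. The probes were chosen for their rise over the same control arrays, so a difference above 0 is expected in part from the shared controls. The higher of the ratios to bisphenol A was 0.339, and 6 of the 9 differed from bisphenol A in each of the other chemicals, so whether the other chemicals may raise the same probes to a smaller extent was not settled.

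Of 2840 negative control spots, 4.15% were well above background on the 18 exposed arrays and 4.06% on the 6 control arrays, a difference of 0.0900 percentage points, below the SD of 0.433 over the arrays.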
